A study of Mus musculus with 4 samples.

How the data were processed

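The series holds 4 arrays, of colonic epithelial cells from 2 mice on a low fiber diet (LFD 1 and LFD 2) and 2 mice on a high fiber diet (HFD 1 and HFD 2). Per the labels' protocols, germ-free male BALB/c mice were colonised with CRB at 8 weeks of age, the colon was taken at 12 weeks, epithelial cells were isolated, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of total RNA. The labels do not say how epithelial cells were isolated or whether they were sorted. Per the submitters' processing notes, the authors used RMA, and the deposited values are therefore log2 values of background-corrected, normalized probe sets; software, version and which arrays were processed together are not stated.

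The values gave more detail on the processing. LFD 1 shared an identical value with another array in 0 of 35557 probe sets, while LFD 2, HFD 1 and HFD 2 shared identical values in 43.3% to 49.0% of probe sets per pair, and 13759 probe sets (38.7%) were identical on all 3. The median of LFD 1 was 6.86 and the others were 7.02, 7.03 and 7.05. The deposited normalization was kept for the main results, and median centring and quantile normalization were run as alternatives.

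Of the probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 were not in it; only those with 1 symbol were named. Symbols were updated through the Entrez gene ID with a gene table of assembly GRCm38.p6, which held 21698 of these probe sets' IDs and lacked 91; those kept the annotation's symbol. No coordinates are given, since the build behind the array is not named. A gene with several probe sets (999 of 19938 genes) was represented by the one with the highest mean over the 4 arrays. Genes whose mean lay at or under the 40th percentile of all probe sets (6.47) were left out as dim, leaving 13377.

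HFD and LFD were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, without trend, robust or block), with Benjamini-Hochberg adjustment over all genes kept and a threshold of adjusted p under 0.05. The residual degrees of freedom were 2 and the prior ones 2.00. Standard errors are limma's moderated ones. Many genes have identical values on both HFD arrays (6737 of those kept), which lowers their estimated spread. Groups that do not overlap were found in 3429 genes (25.6%). Chance gives 33.3% for distinct values, but 4800 genes (35.9%) were identical on LFD 2, HFD 1 and HFD 2 and overlap by construction, so these shares cannot be compared.

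Before the data were examined, 41 lists of pathway genes, epithelial cell type genes and markers of other cell types were fixed, with 773 genes in all, of which 64 were missing from the 1-symbol annotation. Lists with at least 5 genes kept (39) were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Alternatives were camera with an estimated correlation and fry, whose directional p asks whether a list's genes move one way on balance and whose mixed p whether they change in either direction. List medians and means are of log2 HFD minus LFD, relative to the median and mean of all genes. The named genes followed a rule fixed at the same time. In each direction it takes the 12 genes with the largest difference among those past the threshold whose groups do not overlap, with free places filled by genes with an unadjusted p under 0.05 and non-overlapping groups; clone and predicted names are passed over. It adds up to 4 passing members per list, or the 2 members with the largest difference where none passes, and a set of fixed genes of the colon's response to fiber and of sex. Since no gene passed, all 24 places were filled. Of the fixed genes, Ddx3y was not analysed here.

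The test was tried on simulated data for this comparison, with 13377 genes at the measured means and spread and 50 genes changed at each fold. The test recovered 0% of the genes changed 1.5-fold, 32.0% of those changed 2-fold, 84.0% of those changed 4-fold and 90.0% of those changed 8-fold. It made 8 false calls. The simulated arrays had no identical HFD values and no offset of LFD 1, so these shares need not hold for the measured arrays. In simulated lists of 20 genes, camera with the preset correlation called 0 of 38 unshifted lists when genes were independent and 22 of 38 when the members of a list shared a random array effect.

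Other settings fixed beforehand were the filter (none, or the 60th percentile), an offset of 50 before log2, both scalings, other rules for several probe sets, eBayes with trend or robust, a test without moderation, the replicate number as a block, each array left out, other thresholds and the other list tests. Leaving out 1 LFD array leaves only the HFD pair to give the spread, so genes with identical HFD values have no residual. These fits were run on all genes and, as an addition made after their counts were seen, on the 6640 genes with different HFD values; the values given without LFD 1 or LFD 2 are from the second kind unless stated. Further additions made after seeing the data were quantile normalization together with leaving out an LFD array, and leaving out genes with identical HFD values from the fit of all 4 arrays. A lone array in such a fit is assumed to vary like the other group.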

Results

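RNA of isolated colonic epithelial cells was hybridised to 4 Affymetrix arrays, 1 for each of 4 male BALB/c mice. The mice were raised germ-free, received CRB by mouth at 8 weeks of age, and then ate their diet for 4 weeks. The labels do not expand CRB. A low fiber diet (LFD) was given to 2 mice and a high fiber diet (HFD) to the other 2. The comparison asks which epithelial transcripts differ with the fiber in the diet of such mice. The values are RMA values on the log2 scale, and the number of arrays limits their precision. The median over 35557 probe sets was 6.86 on LFD 1, 7.02 on LFD 2, 7.03 on HFD 1 and 7.05 on HFD 2. Over the 13377 genes tested, the median gene lay 0.11 higher in HFD than in LFD. Gene list medians are given relative to that median gene, while values of single genes include this shift. A difference of a single gene can also rest on LFD 1 alone, where LFD 2 and the HFD arrays have equal values. Male labels matched the arrays: Kdm5d and Eif2s3y, which lie on the Y chromosome, had mean values of 8.07 and 8.67 in LFD and 8.43 and 9.27 in HFD. Xist, the RNA of the inactive X chromosome, was at 5.79 in LFD and 5.47 in HFD, under the dim limit of 6.47.

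The 24 leading genes had the largest differences, 12 in each direction, among genes with non-overlapping groups and an unadjusted limma p under 0.05. Clone and predicted names were passed over. These 24 included Retnlb, Itln1 and Ang4, with higher values in HFD, and Cd74, H2-Ea, Mcpt1 and Mcpt2, with lower values. Retnlb, which encodes the goblet cell protein RELM-beta, had a mean value of 12.76 ± 0.25 in HFD and 9.74 ± 1.81 in LFD (SD, n = 2 each). Cd74, the invariant chain of class II molecules, had a mean value of 10.18 ± 0.03 in HFD and 12.29 ± 0.58 in LFD (SD, n = 2 each). As groups, cholesterol synthesis, chaperone, cell cycle, goblet and tuft cell genes were placed above the other genes in HFD by camera. Antigen presentation and chemokine genes were placed below them. The calls of cell cycle, goblet and tuft cell genes ended without LFD 2, with medians of 0.10, 0.13 and 0.23. After quantile normalization goblet cell genes were called without LFD 2 as well. No single gene passed the threshold of the limma test (adjusted p under 0.05), and no gene list passed with an estimated inter-gene correlation.

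Among the 12 leading genes above LFD, 3 encode secreted goblet cell or Paneth-type defence proteins. These are Retnlb, at 3.02 ± 0.91 (log2 HFD minus LFD ± SE), Itln1, a lectin that binds microbial sugars, at 2.99 ± 0.97, and Ang4, an antimicrobial ribonuclease, at 2.44 ± 0.52. The largest difference of the 12 was that of Pla2g4c, a phospholipase A2, at 3.40 ± 0.81. Emp1, a membrane protein of surface epithelium, stood at 2.97 ± 0.78 and Isx, an intestinal homeobox factor that represses carotenoid uptake and cleavage genes, at 2.77 ± 0.62. The surface proteins Ly6g6c, Plet1 and Ly6m lay at 2.71 ± 0.41, 2.68 ± 0.51 and 2.66 ± 0.48. Sptssb, a subunit of serine palmitoyltransferase, was at 2.47 ± 0.28. B4galnt1, which makes gangliosides, and B3gnt6, which makes core 3 mucin-type glycans, were at 2.37 ± 0.38 and 2.26 ± 0.38. The adjusted p-values of these 12 genes, from limma with Benjamini-Hochberg adjustment, lay between 0.183 and 0.501, so none passed. All 12 were lower on LFD 2 than on LFD 1, and Retnlb spanned 8.46 to 11.02 between these arrays.

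Among the 12 leading genes below LFD, Cd74 at -2.10 ± 0.30 and H2-Ea at -2.17 ± 0.33 belong to class II antigen presentation. Mcpt2 at -3.10 ± 0.64 and Mcpt1 at -2.36 ± 0.65 are proteases of mucosal mast cells. S100g, the vitamin D-induced calcium carrier calbindin-D9k, had the lowest difference of the 12, -3.26 ± 0.73. The sialyltransferase St8sia5 was at -3.06 ± 0.38, the metalloreductase Steap4 at -2.48 ± 0.67 and the sterol exporter subunit Abcg5 at -2.41 ± 0.61. Slc30a10, a manganese exporter, stood at -2.32 ± 0.34, Casp14 at -2.27 ± 0.52 and the secreted Wnt inhibitor Sfrp1 at -2.16 ± 0.73. Nr1d1, the clock repressor REV-ERB alpha, was at -2.15 ± 0.58. The adjusted p-values of these 12 genes lay between 0.183 and 0.536, so none of them passed either. Genes whose groups overlapped were left out even where their difference was larger than some of these. Pancreatic enzyme genes high on LFD 2 were among those left out, such as Cel at -2.66, Try5 at -2.62 and Cpa1 at -2.56.

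**Figure D1:**
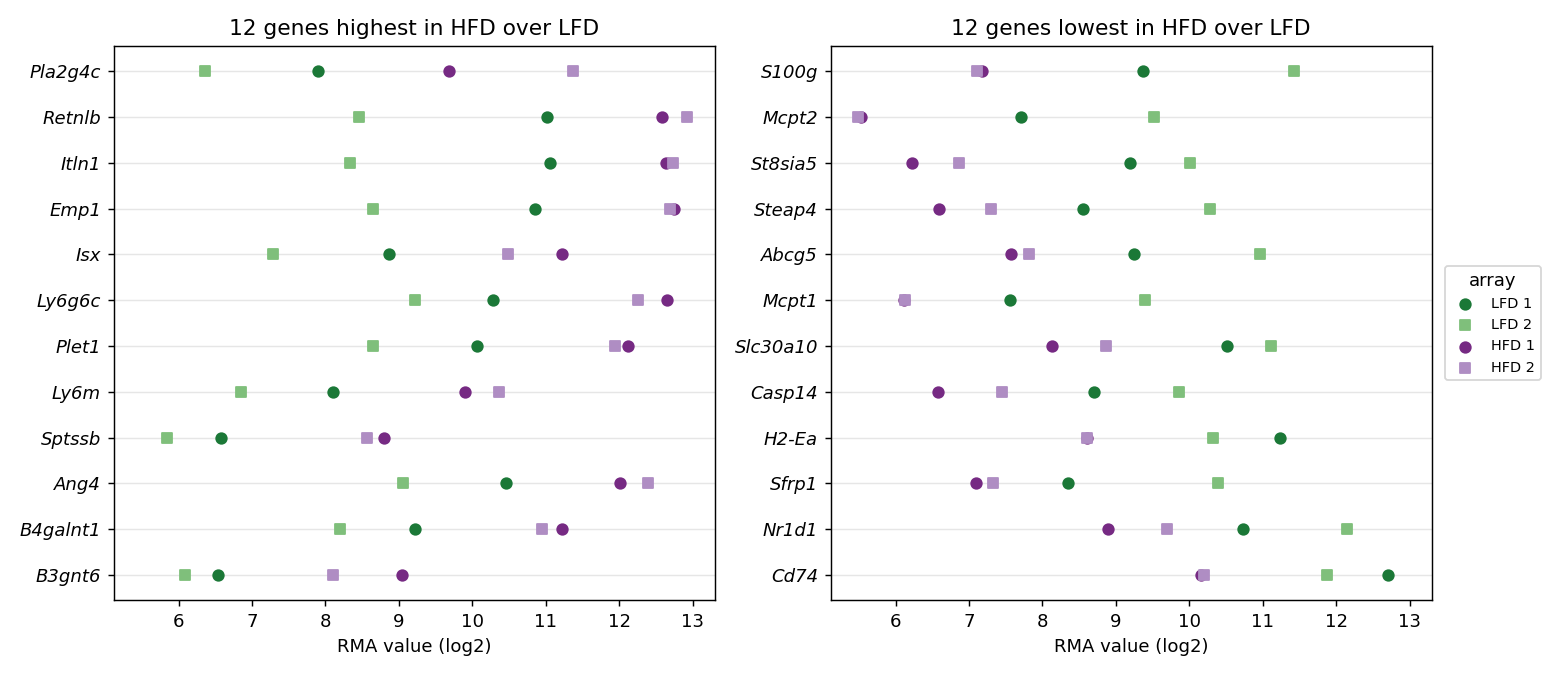
RMA values (log2, horizontal axis) of the 12 leading genes above LFD and the 12 leading genes below LFD. They have the largest differences among genes with non-overlapping groups and an unadjusted limma p under 0.05. Each point is 1 array, green for LFD and purple for HFD, circles for replicate 1 and squares for replicate 2. LFD 2 lies farther from the HFD arrays than LFD 1 in all 12 genes at left; at right, Cd74 and H2-Ea have LFD 1 farther.

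Over all genes, 0 of 13377 passed in limma and 0 in an equal-variance test without moderation. By chance 669 genes would be expected to have an unadjusted p under 0.05. Such a p was found for 1149 genes in limma, 1003 of them higher in HFD and 146 lower, and for 766 genes in the equal-variance test. Quantile normalization of the arrays removes the offset of LFD 1. After it 1582 genes had such a p, 916 higher and 666 lower, and again 0 passed after adjustment. The lowest adjusted p was 0.105, shared by 3 genes picked out here after their values were seen. Cyp2c65 and Cyp2c55, cytochrome P450 enzymes of lipid and drug oxidation, were at 2.16 ± 0.08 and 2.05 ± 0.09 (log2 HFD minus LFD ± SE), and Glp1r, the GLP-1 receptor, was at 1.91 ± 0.09. At least a 2-fold difference, non-overlapping groups and an unadjusted p under 0.05 came together in 115 genes higher in HFD and 37 lower. The count of passing genes depended on which genes and arrays entered. With the 6737 genes whose 2 HFD values are identical left out, 66 genes passed, 57 higher and 9 lower, among them 5 of the 24 genes above. Without HFD 1 147 genes passed and without HFD 2 146; without LFD 1 the count was 709 and without LFD 2 2849 once identical HFD values were left out, and 7189 and 7873 over all genes, many of which then have no residual.

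Secretory and sensory cell lists lay above the median gene. Goblet cell genes had 17 of 19 members above it and a median of 0.32 (camera adjusted p = 1.11e-09; adjusted p = 0.521 with an estimated correlation). Of these genes 9 passed when adjusted over the list alone, all higher, and 4 did so after quantile normalization; Tpsg1 was at 1.16 (log2 HFD minus LFD) next to Retnlb, while Muc2, the main colonic mucin, was at 0.24. All 7 deep crypt secretory cell genes lay above the median gene, with a median of 0.37 (camera adjusted p = 2.48e-05; adjusted p = 0.521 with an estimated correlation), and 5 passed adjusted over the list alone. Their leading member after Retnlb was Mptx1, at 1.55. Tuft cell genes, led by Dclk1 at 1.32 and Trpm5 at 1.05, had 9 of 12 members above it and a median of 0.40 (camera adjusted p = 0.000163; adjusted p = 0.521 with an estimated correlation). Of the tuft genes 7 passed adjusted over the list alone and 1 did so after quantile normalization; fry's directional test called this list alone of the 39 tested (adjusted p = 0.0384). Enteroendocrine cell genes had 13 of 14 members above it and a median of 0.14 (camera adjusted p = 0.00922; adjusted p = 0.835 with an estimated correlation), with the prohormone convertase Pcsk1 at 1.38 and Gcg, the precursor of GLP-1, at 0.80; both passed adjusted over the list alone. Without LFD 2 the calls ended for goblet (adjusted p = 0.0588), deep crypt (0.222), tuft (0.0855) and enteroendocrine genes (0.0544), and without LFD 1 for enteroendocrine genes (0.0559). The medians without LFD 2 were 0.13 for goblet, 0.30 for deep crypt, 0.23 for tuft (8 members left) and 0.62 for enteroendocrine genes (9 members left), and 0.14 for enteroendocrine genes without LFD 1. After quantile normalization without LFD 2, goblet, deep crypt and enteroendocrine genes were called and tuft cell genes were not (adjusted p = 0.0699). Over all alternatives of data or fit the adjusted p ran from 5.80e-17 to 0.0588 for goblet, 1.95e-16 to 0.222 for deep crypt, 1.06e-06 to 0.0855 for tuft and 2.01e-05 to 0.0573 for enteroendocrine genes.

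Surface colonocyte genes were not called as a list by camera (adjusted p = 0.521, median 0.04, 11 of 22 above the median gene) but were by fry's mixed test (adjusted p = 0.0148). Of its members, 6 were higher and 1 lower adjusted over the list alone, and 3 were higher and 2 lower after quantile normalization. They became called without LFD 1 (adjusted p = 0.0103), without HFD 1 (0.000133) and without HFD 2 (4.99e-09), with medians of 0.25, -0.03 and 0.15. Over the alternatives the adjusted p ran from 4.99e-09 to 0.616. Emp1 and Cyp2c55 lead this list, and the surface carbonic anhydrase Car4 was at 0.00. Crypt base and stem cell genes had a median of -0.02 (camera adjusted p = 0.791; fry's mixed test, adjusted p = 0.0148), and 1 of 18 members, Cd44 at 0.84, passed adjusted over the list alone. Prom1 was at 1.61 and the stem cell marker Lgr5 at -0.10. The list's median was negative, its mean was 0.10 and its test pointed up.

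Cell cycle genes had 27 of 31 members above the median gene and a median of 0.26 (camera adjusted p = 3.68e-10; adjusted p = 0.521 with an estimated correlation). The replication helicase subunit Mcm6 was at 0.96 and the ribonucleotide reductase subunit Rrm2 at 0.74. Of the cell cycle genes 14 passed adjusted over the list alone, all higher, but 1 did so after quantile normalization, and without LFD 2 the list's call ended (adjusted p = 0.559, median 0.10), with a range of the adjusted p of 2.89e-12 to 0.559 over the alternatives. The unfolded protein response and ER chaperone list had 21 of 23 members above the median gene and a median of 0.26 (camera adjusted p = 3.89e-09; adjusted p = 0.521 with an estimated correlation). Here 13 members passed adjusted over the list alone and 8 after quantile normalization; the largest differences were those of asparagine synthetase, Asns, at 0.96, and Chac1 at 0.69, both induced by amino acid shortage through ATF4.

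Cholesterol biosynthesis and uptake genes had the highest median of the lists tested, 0.51, with 17 of 18 members above the median gene (camera adjusted p = 3.74e-09; adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone, 10 members passed, all higher, and 10 after quantile normalization; Lss, lanosterol synthase, was at 1.23 and Cyp51, lanosterol demethylase, at 0.96. Fatty acid and triglyceride synthesis genes had a median of 0.15 (camera adjusted p = 0.0389; adjusted p = 0.835 with an estimated correlation), with 3 members higher and 1 lower adjusted over the list alone. Me1, malic enzyme, was at 1.29 and the desaturase Fads1 at 0.82. Xenobiotic metabolism genes had a median of 0.22 (camera adjusted p = 0.00922; adjusted p = 0.835 with an estimated correlation). They were led by Cyp2c65 and Cyp2c55, and 5 of 19 passed adjusted over the list alone, all higher. After quantile normalization 8 passed as higher and 2 as lower. Fatty acid synthesis and xenobiotic genes lost their calls with all 4 arrays once genes with identical HFD values were left out (adjusted p = 0.197 and 0.115), and under the stricter filter (0.317 and 0.162). They were not called in the fits that also left out LFD 1 (0.319 and 0.123) or LFD 2 (0.559 and 0.586), so these losses cannot be put down to 1 array. Fatty acid synthesis genes lost their call without HFD 2 as well (0.0870). For fatty acid synthesis the median was 0.15 without LFD 2 and 0.14 without HFD 2, near the 0.15 of all arrays, and 0.05 without LFD 1; for xenobiotic genes it was 0.07 without LFD 1 and 0.15 without LFD 2. Over the alternatives their adjusted p ran from 0.00591 to 0.559 and from 1.08e-08 to 0.586.

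Of the lists on energy metabolism, glycolysis and hypoxia-induced genes had a median of -0.09 (camera adjusted p = 0.00142; adjusted p = 0.835 with an estimated correlation). Ankrd37, induced by hypoxia, had a mean of 8.16 in HFD and 9.16 in LFD, and Egln3, an oxygen sensor, was at -0.60; 0 of 21 passed adjusted over the list alone, and the call ended without LFD 2 (adjusted p = 0.0815), where the median was farther from 0, at -0.13. The adjusted p ran from 0.000952 to 0.118 over the alternatives. Mitochondrial fatty acid oxidation genes had a median of -0.06 (camera adjusted p = 0.0315; adjusted p = 0.880 with an estimated correlation), with the carnitine carrier Slc25a20 at -0.36 and the thiolase Acaa2 at 0.28. PPAR target genes had a median of -0.14 and a mean of 0.02 (camera, pointing down, adjusted p = 0.0145; adjusted p = 0.521 with an estimated correlation), with Fabp2 at 1.99 and Pdk4 at 0.68. Adjusted over the list alone 0 of 11 PPAR targets passed, and after quantile normalization 2 higher and 4 lower. The calls of these 2 lists ended after quantile normalization (adjusted p = 0.0907 and 0.121) and without any 1 of the 4 arrays, where the adjusted p lay between 0.0544 and 0.368 for fatty acid oxidation and between 0.148 and 0.664 for PPAR targets. Leaving out genes with identical HFD values, as the fits without an LFD array do, ended the PPAR call with all 4 arrays too (0.187). The median of fatty acid oxidation genes stayed between -0.18 and -0.05 in these fits, and that of PPAR targets between -0.32 and -0.13 except without LFD 2, where it was 0.09. Over all alternatives the ranges were 0.0305 to 0.368 and 0.0130 to 0.961. Oxidative phosphorylation genes had a median of -0.03 (camera adjusted p = 0.414; Ndufa4 at 0.37, Ndufa9 at 0.18) and gluconeogenesis genes one of 0.02 and a mean of -0.09 (adjusted p = 0.521; Ppargc1a at -0.55, Pck2 at 0.28). Ketone body metabolism had 4 genes kept and was not tested; Aacs was at 0.53 and Oxct1 at -0.25.

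Short-chain fatty acid receptors and transporters had a median of -0.07 and a mean of 0.18 (camera, pointing up, adjusted p = 0.922; fry's mixed test, adjusted p = 0.0206). Adjusted over the list alone 2 of 8 passed, both higher: Slc16a7, a monocarboxylate transporter, at 1.81 and Ffar2, a receptor of short-chain fatty acids, at 0.88. The transporters Slc5a8 and Slc16a1 were at 0.03 and -0.01. Hcar2, Angptl4 and Reg3g lay under the dim limit and were not tested. Tgfb1 was at 0.31 ± 0.19 (SE, limma adjusted p = 0.692). Its values were 7.11 on LFD 1, 7.61 on LFD 2 and 7.67 on both HFD arrays, so most of the difference rests on LFD 1. The list of TGF-beta ligands, activators and receptors had a median of -0.02 (camera adjusted p = 0.770, and fry's mixed test, adjusted p = 0.0224). In that list Thbs1, which activates latent TGF-beta, was at 1.16, passed adjusted over the list alone, and Skil was at -0.36. Epithelial factors acting on regulatory T cells had a median of -0.02 (camera adjusted p = 0.0686; fry's mixed test, adjusted p = 0.0206). Aldh1a1, which makes retinoic acid, was at 2.04 and Ido1, which degrades tryptophan, at -1.97, and both passed adjusted over the list alone. After quantile normalization 1 member passed as higher and 3 as lower. This list became called without HFD 1 (adjusted p = 0.0308) and with genes of identical HFD values left out (0.0494), in a range of 0.0308 to 0.410 over the alternatives. Histone deacetylases and acetyltransferases had a median of 0.02 (camera adjusted p = 0.778), with Hdac1 at 0.37 and Hdac3 at 0.33.

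Antigen presentation lay below the median gene in HFD. Class II antigen presentation genes had 8 of 9 members below it and a median of -0.70 (camera adjusted p = 4.20e-12; adjusted p = 0.521 with an estimated correlation). Adjusted over the list alone, 5 members passed, all lower, among them Cd74 and H2-Aa at -2.10 and -2.08. All 9 class I antigen presentation genes lay below it, with a median of -0.34 (camera adjusted p = 3.89e-09; adjusted p = 0.521 with an estimated correlation). The immunoproteasome subunit Psmb8 was at -0.68 and the peptide transporter Tap1 at -0.66; adjusted over the list alone 0 passed, and 6 did so after quantile normalization, all lower. NF-kappaB targets and chemokines had a median of -0.26 (camera adjusted p = 1.42e-06; adjusted p = 0.521 with an estimated correlation). The T cell attractants Cxcl9 and Cxcl10, at -1.29 and -1.21, were the 2 members that passed adjusted over the list alone. After quantile normalization 4 members passed, all lower. Interferon response genes had a median of -0.06 (camera adjusted p = 0.00326; adjusted p = 0.835 with an estimated correlation), with Mx1 at 1.06 and Gbp3 at -0.70. Adjusted over the list alone, Mx1 passed as higher and Irf1 as lower. That call ended after quantile normalization (adjusted p = 0.332), without LFD 2 (0.494) and without HFD 2 (0.368), with medians of -0.07, 0.17 and 0.09. It held without LFD 1, with a median of -0.42 (adjusted p = 0.000767), and without HFD 1, with one of -0.33 (3.90e-10). Antimicrobial and host defence genes had a median of -0.10 and a mean of 0.08 (camera, pointing down, adjusted p = 0.00614; adjusted p = 0.521 with an estimated correlation). Retnlb and Itln1 had its largest differences, and adjusted over the list alone 1 of 20 passed, Saa1, which was lower. The call ended under the stricter filter (adjusted p = 0.0849), after quantile normalization (0.201), without LFD 1 (0.705) and without HFD 2 (0.344), with medians of -0.08, -0.07, 0.01 and -0.20, and without HFD 1 camera called it in the other direction (0.000636). Tight and adherens junction genes had a median of -0.14 (camera adjusted p = 0.00142; adjusted p = 0.835 with an estimated correlation), with Cldn15 at 1.19 and Cldn8 at -0.43. The junction call ended without LFD 2 (0.0855), HFD 1 (0.330) or HFD 2 (0.429), with medians of -0.19, -0.12 and -0.13, near that of all arrays. Over the alternatives the adjusted p ran from 3.90e-10 to 0.514 for interferon, 0.000636 to 0.797 for antimicrobial and 0.000328 to 0.429 for junction genes.

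**Figure D2:**
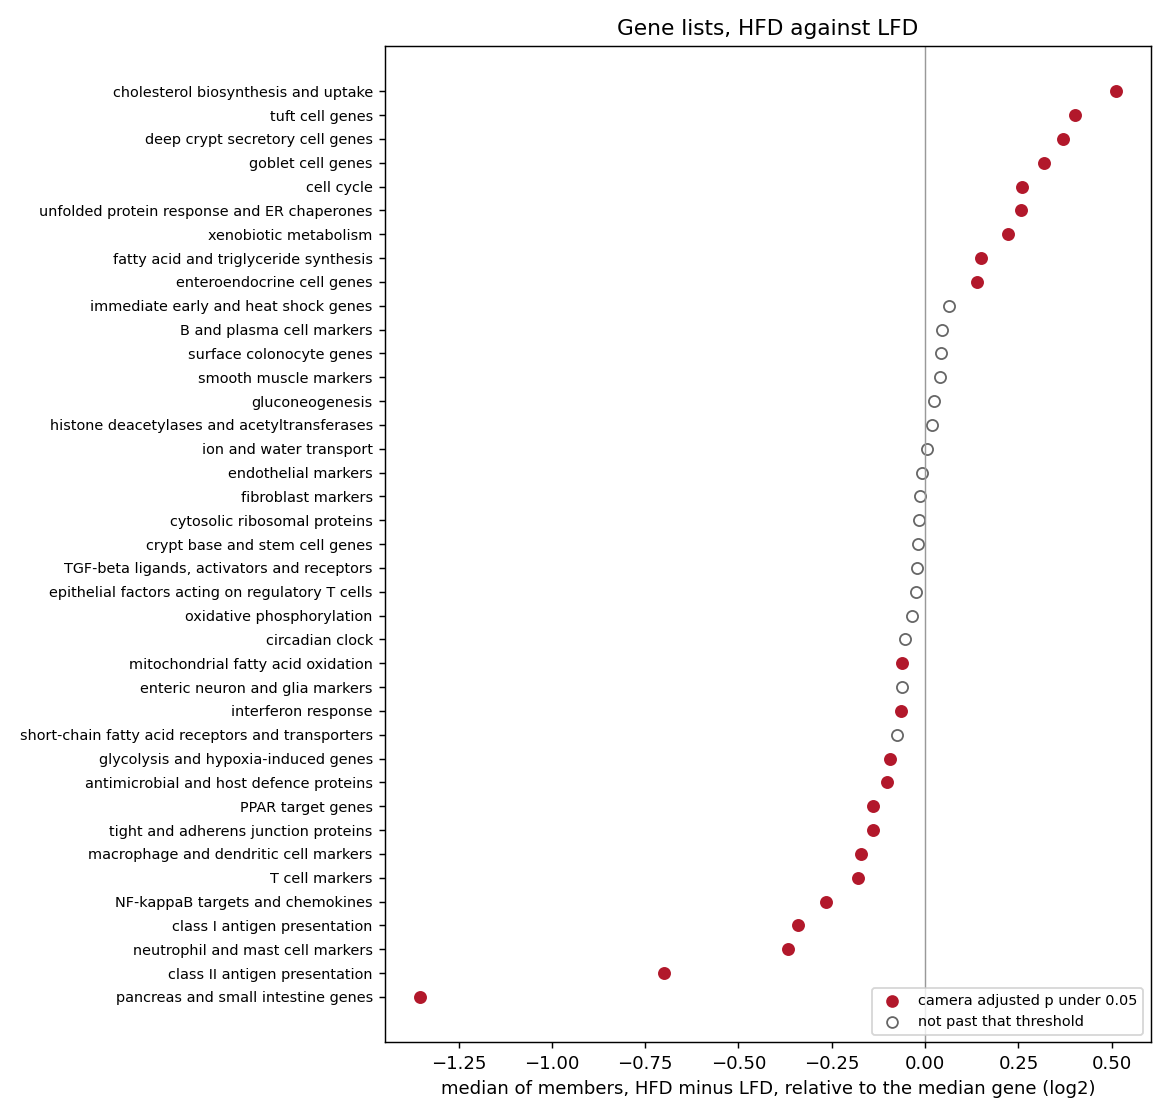
Median of the members of each of the 39 gene lists tested, as HFD minus LFD relative to the median gene (log2, horizontal axis); filled points passed camera's adjusted p of 0.05 with the preset correlation. Medians run from -1.35 for pancreas and small intestine genes to 0.51 for cholesterol biosynthesis and uptake; 0 of the 39 passed with an estimated correlation.

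Markers of other cell types were measured to see what the isolated cells carried along. Neutrophil and mast cell markers had 6 of 6 tested members below the median gene and a median of -0.37 (camera adjusted p = 2.48e-05; adjusted p = 0.521 with an estimated correlation), led by Mcpt2 and Mcpt1. Adjusted over the list alone 0 passed, and 3 did so after quantile normalization, all lower. T cell markers had a median of -0.18 (camera adjusted p = 0.00142; adjusted p = 0.761 with an estimated correlation), with Cd3e at -0.41, which passed adjusted over the list alone, and Cd7 at -0.39, and lost their call without HFD 2 (adjusted p = 0.0750) with the median still at -0.18. Macrophage and dendritic cell markers had a median of -0.17 (camera adjusted p = 0.0151; adjusted p = 0.835 with an estimated correlation), with Lyz2 at -0.63 and Cd14 at -0.32. Their call ended after quantile normalization (0.101), without LFD 2 (0.219) and without HFD 1 (0.0862), with the median at -0.17 in each. Over the alternatives the adjusted p ran from 0.00115 to 0.0926 for T cell and from 0.00927 to 0.219 for macrophage and dendritic cell markers. The lists of class II, chemokine, mast cell, T cell and macrophage genes thus all had medians below the median gene. B and plasma cell markers had a median of 0.04 (camera adjusted p = 0.695; fry's mixed test, adjusted p = 0.0224; Derl3 at 0.96, Jchain at 0.65). Fibroblast markers (median -0.01, adjusted p = 0.742; Dcn at 0.34, Fbln1 at 0.18) were not called, nor were endothelial markers (median -0.01, test pointing up, adjusted p = 0.983; Plvap at 0.33, Cdh5 at 0.19). Smooth muscle markers (median 0.04, adjusted p = 0.922; Smtn at 0.32, Mylk at -0.24) and enteric neuron and glia markers (median -0.06, adjusted p = 0.742; Snap25 at 0.46, Ret at 0.17) were not called either. Plvap, Cdh5 and Ret had equal values on LFD 2, HFD 1 and HFD 2, so their differences rest on LFD 1. Among red blood cell markers only Slc4a1, at 0.07, was above the dim limit, so the list was not tested.

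Pancreas and small intestine genes had a median of -1.35 (camera adjusted p = 0.00510; adjusted p = 0.684 with an estimated correlation), with LFD 2 far from the other arrays. The trypsinogen gene Try5 was at 12.33 on LFD 2 and between 6.17 and 7.34 on the other arrays, and the carboxypeptidase gene Cpa1 at 13.25 against 7.19 to 8.17. Without LFD 2 the median was 0.23 (adjusted p = 0.336), and after quantile normalization the call ended (0.350) with the median still at -1.34. The adjusted p ran from 2.46e-39 to 0.855 over the alternatives. The goblet, deep crypt, tuft and cell cycle lists, which lost their calls without LFD 2, were lowest on that array: relative to the gene means after quantile normalization, their means on LFD 2 were -0.49, -0.75, -0.34 and -0.26. Enteroendocrine genes, whose call also ended without LFD 2, and fatty acid synthesis and xenobiotic genes were instead lowest on LFD 1, at -0.27, -0.15 and -0.23, against -0.04, -0.04 and -0.15 on LFD 2.

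**Figure D3:**
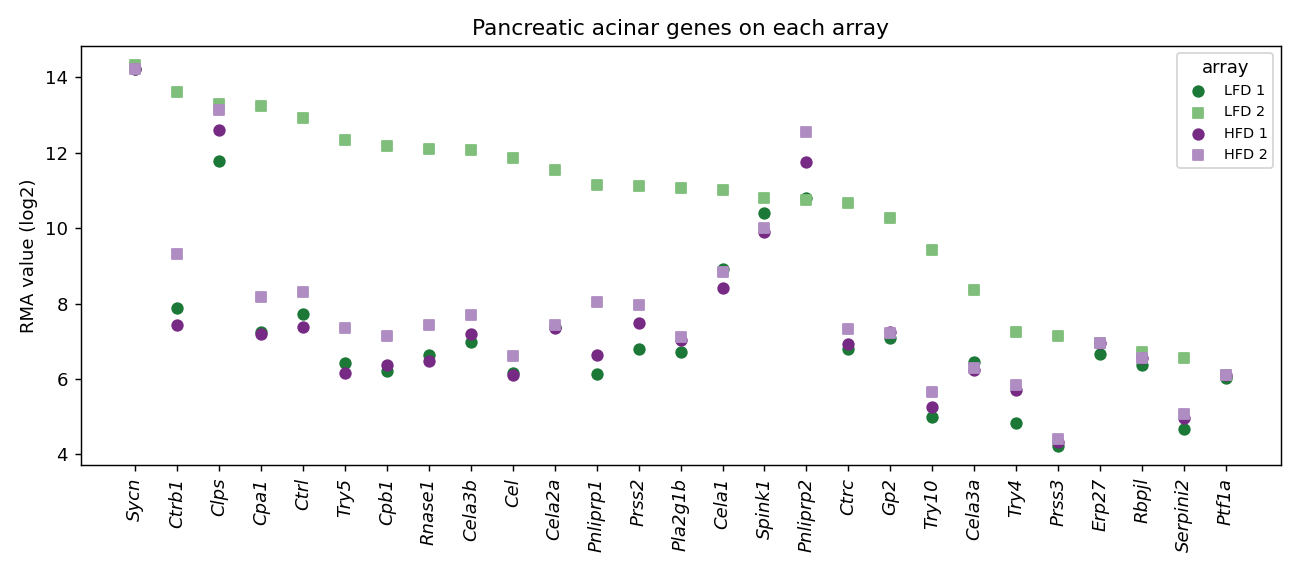
RMA values (log2, vertical axis) of 27 pancreatic acinar genes, listed after the high values on LFD 2 had been seen; each point is 1 array, green for LFD and purple for HFD, circles for replicate 1 and squares for replicate 2. On LFD 2, 25 of the 27 genes lie above the mean of the other arrays after quantile normalization.

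The remaining lists were not called by camera. The circadian clock list had a median of -0.05 (camera adjusted p = 0.0620), with Nr1d1 lowest and Ciart at 0.54. Ciart was at 5.82 on LFD 1 and at 6.90 on each other array, so its difference rests on LFD 1. The clock list became called with the mean of a gene's probe sets (camera adjusted p = 0.0341) and with the replicate block (0.0198). The clock list was also called without HFD 1, with a median of -0.09, and without HFD 2, with a median of -0.02. Ion and water transport genes had a median of 0.00 and a mean of -0.06 (camera, pointing down, adjusted p = 0.371, and fry's mixed test, adjusted p = 0.0206). Adjusted over the list alone, 4 members were higher and 2 lower, and after quantile normalization 3 were higher and 6 lower. The chloride channel regulator Clca4a was at 2.08 and the sodium channel subunit Scnn1g at -1.76. That list became called without LFD 2 (0.0175). Immediate early and heat shock genes had a median of 0.07 (adjusted p = 0.226; Dusp1 at -0.83, Fosb at 0.78) and became called without HFD 2 (0.0280). Over the alternatives the adjusted p ran from 0.0153 to 0.665 for clock, 0.0175 to 0.858 for transport and 0.0280 to 0.789 for immediate early and heat shock genes. Cytosolic ribosomal protein genes had a median of -0.02 (adjusted p = 0.953; Rpl30 at 0.28, Rps4x at 0.19). Over all 39 lists camera called 22, 9 up and 13 down. After median centring and after quantile normalization it called 16 each, 9 up and 7 down. There were 0 called under an estimated correlation, where the lowest adjusted p was 0.521. In that test 2 lists, class II and tuft cell genes, had an unadjusted p under 0.05. Their estimated correlations, -0.005 and -0.087, lay under the preset 0.01. For these 2 lists the loss of the call thus does not come from a higher correlation among members. On simulated data in which the genes of a list shared a random array effect, the preset correlation called 22 of 38 lists that had no shift. The estimated correlation called 0 of these lists. Whether it would call a shifted list was not examined, so its 0 calls do not show that it can find a shift.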

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

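The fits that join quantile normalization with a left-out array, or that leave out genes with identical HFD values, were chosen after seeing the data. The count of 0 passing genes did not change with the filter, the offset, either scaling, the rule for probe sets, trend, robust or no moderation, the looser threshold, the fold limits, or quantile normalization without LFD 2. Leaving out 1 array gave between 146 and 7873 genes, the latter over all genes with many lacking a residual; with identical HFD values left out it was 709 without LFD 1 and 2849 without LFD 2. Quantile normalization without LFD 1 gave 383 genes and leaving out identical HFD values with all arrays gave 66. The 2849 genes without LFD 2 were 2694 higher and 155 lower, with the median gene at 0.23, and 0 passed in that fit after quantile normalization, with the median gene at 0.03, so the offset of LFD 1 enters that count. Causes other than this offset and genes without a residual were not tested. With the replicate block 500 genes passed, where the main count is 0. LFD 1 and HFD 1 deviated together across genes with r = 0.07. With only 2 shared numbers this cannot tell what the numbers mark, which the labels do not say.

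Against 22 called lists, 1 array left out gave between 2 and 21 lists, with 8 without LFD 2 and identical HFD values left out, and 8 after quantile normalization without LFD 2. Camera with an estimated correlation gave 0 and fry's directional test 1; fry's mixed test gave 19. Cholesterol, class I, class II, NF-kappaB, and chaperone lists kept their calls in 17 of 17 alternatives of data or fit. Neutrophil and mast cell markers kept theirs in 11 of 11. Both counts include the looser threshold of 0.1 on the main fit, under which no call can be lost. The neutrophil and mast cell list had too few members once genes with identical HFD values were left out. Its 11 alternatives therefore hold no fit without LFD 1 or LFD 2. The fits without LFD 1 or LFD 2 over all genes, which called 2 and 4 lists, are not among these. Results that turned direction, given as medians relative to the median gene, with causes not tested: PPAR targets with the replicate block (-0.14) and without HFD 2 (-0.14); antimicrobial genes with the block (-0.10) and without HFD 1 (-0.0761, against -0.204 without HFD 2); interferon response genes without HFD 2 (0.0872, against -0.334 without HFD 1), in fry's directional test (-0.0649) and after quantile normalization without LFD 2 (0.15); fatty acid oxidation in fry (-0.0606); pancreas and small intestine genes after quantile normalization without LFD 2 (0.25). Directions are those of the test, which can differ in sign from the median. They were compared only where the main or the alternative fit called the list. Among the other list values, 117 lost and 22 gained a call, and 599 stayed on the same side of the threshold. The direction of a list uncalled in both fits was not compared. Of named genes 348 values gained a call, and 1333 did not, none turning direction while called. The alternative restricted by probe set suffix was not run, since no probe set here carries one. Values near the dim limit carry little signal over background.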

Other observations

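The tests of the arrays' processing, of pancreatic and small intestinal RNA, of separate processing as a cause of the leading differences and of LFD 2 against LFD 1 were chosen after the values were seen; the test of colon position between diets and the count of other splits were planned before.

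Interferon response genes differed between mice of the same diet more than between diets. After quantile normalization the mean of this list, relative to the gene means, was 0.43 on LFD 2 and 0.17 on HFD 1 but -0.27 on LFD 1 and -0.33 on HFD 2. Ifit1, picked out after its values were seen, was at 9.20 and 8.48 on the first pair and at 7.73 and 7.25 on the second; Oas2 was at 9.11 and 8.55 against 7.61 and 7.40. The list of immediate early and heat shock genes differed less, at 0.14 on HFD 1 and -0.06 on HFD 2. Its members Hspa1a and Hsph1, also picked out after their values were seen, were at 12.70 and 11.30 on HFD 1 and at 11.40 and 10.21 on HFD 2. Both LFD mice lay between these for each gene, with Hspa1a at 11.97 and 11.98 and Hsph1 at 10.45 and 10.77. No test separates these differences between single mice from those between arrays.

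LFD 1 is offset from the other arrays, which share exact values: in the pair sharing least, 43.3% of probe sets were identical, against 0% in each pair with LFD 1. Median polish on simulated probe sets gave identical values on all arrays in 65.5% of probe sets when 3 arrays were summarised together, and any identical pair in 0% when 4 were. A candidate explanation is that LFD 1 was summarised by RMA apart from the other 3. A single RMA run over all 4 arrays, with truly lower RNA levels in LFD 1, is argued against by its median, which lay 0.16 or more from each other median while the others lay within 0.03. Whether LFD 1 was also hybridised apart stays open.

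Pancreatic enzyme genes are high on LFD 2: after quantile normalization the median acinar gene lay 3.60 above the mean of the other arrays (25 of 27 higher, 17 of them at least 4-fold), with Ctrb1 at 13.63 and Cpa1 at 13.25 as deposited; pancreatic tissue RNA in that sample may account for this. Of the 27 genes, Sycn, Clps, Pnliprp2 and Spink1 were at 9.89 or more on every array. Whether small intestinal tissue RNA was present stays open: the median enterocyte gene lay 0.0894 above the others, but members went both ways, with 13 of 20 higher, Enpep by 1.49 and Anpep by 0.96, and Fabp2 at -2.18 and Alpi at -1.91. HFD 2 stood 0.41 above HFD 1 in the median acinar gene, with 22 of 27 higher. Expression of these genes by the colon itself was not tested.

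The 12 leading genes above LFD are graded, lowest on LFD 2, then LFD 1, then both HFD arrays. Separate processing of LFD 1 is argued against as the sole cause of such differences: the 12 genes with the largest HFD 1 minus LFD 1, of which 5 are among the 12 leading genes, lay 1.998 higher on HFD 2 than on LFD 2 in the median, 10 of 12 higher, the exceptions being immunoglobulin kappa variable genes. Whether cells came from different stretches of the colon stays open: the median of 9 posterior Hox genes differed by 0.0822 between HFD and LFD (4 of 9 lower in HFD) and by 0.10 between LFD 2 and LFD 1 (5 of 9 higher on LFD 2), relative to all genes. The bound set beforehand against the first was met, but members went both ways by more than that (Hoxb13 at -0.63, Hoxd13 at -0.84, Hoxa11 at 0.66), so such a median decides nothing, a reading adopted after these values were seen. The diet itself stays among the open explanations.

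The 4 arrays can be parted into 2 and 2 in only 3 ways, too few for a share under 0.05. Of these splits 1, that of the diets, gave 22 gene lists past the camera threshold, and the highest of the others gave 8. At an unadjusted p under 0.05, the diets gave 1149 genes and the other splits 46 and 81, where 669 would be expected by chance. Each of the other splits has 1 array of each diet in either group. The diet difference thus adds to their spread, and their counts are no measure of chance.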
